A study of Mus musculus with 5 samples.

How the data were processed

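RNA was sequenced from haematopoietic stem and progenitor cells sorted from bone marrow of C57BL/6 mice at postnatal day 15. The sorted population was Lin−Sca-1+Kit+ (LSK), the marrow fraction that holds stem cells and multipotent progenitors, with about 12000 cells per library. 5 libraries were analysed, 2 from wild-type (WT) mice and 3 from mice null for Gabbr1, which encodes a subunit of the GABA-B receptor. The labels give 4 animals per genotype in the extraction protocol and 2 and 3 in the series design, and the 5 libraries listed match the design. No label states that each library came from its own animal, so p-values measure the spread between these libraries. Sex, litter and day of sort are not given in the sources used here.

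Per the labels' protocols, between 3.6 and 5 ng of RNA entered a low-input kit that depletes ribosomal RNA with mouse probes, and libraries were read as 2 reads of 50 bp per fragment. The molecule field of the labels says polyA RNA, which differs from that protocol. Per the submitters' processing notes, STAR, featureCounts and the mm10 build were used, and versions are not given in the sources used here. The authors deposited whole-number counts per gene, with 1 column per library and no normalization. The annotation release, the strand setting and the treatment of reads with several matches or of PCR copies are not given in the sources used here. Genes with near-identical copies (histones, Vpreb1 and Vpreb2, immunoglobulin segments) and genes whose exons overlap another gene are therefore uncertain where reads could be split. Of the named genes, Col10a1, Tnc, Dusp1, Junb, Nfkb2, Rag1, Rag2, Rb1, Itga4, Kctd12, Vpreb1, Atf5, Ccna2, E2f8, Ms4a6c, Rrp9, Ube2c and Xist have such an exon overlap in the annotation.

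The table held 39056 genes, and each row named a gene. 99.5% of the identifiers matched GENCODE release M21 on mm10 when their version was ignored, and symbols and coordinates were taken from that release. 11 entries of the fixed gene lists matched no gene. Total counts ranged from 6972753 to 8150774 per library, so that 1 CPM stood for about 7 to 8 counts. Intervals from counts cover counting error only.

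Genes were kept with filterByExpr by group, which left 13467. Counts were scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with genotype as the only term and 3 residual degrees of freedom. Log2 fold changes are null over WT, standard errors were derived from the F statistic, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. CPM values are TMM-normalised and group values are means with SD (WT n = 2, null n = 3). For genes with no WT count a lower bound of the fold was computed against 3 counts over the WT group, and for 1 to 3 WT counts a ratio with an exact 95% binomial interval.

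39 gene lists were fixed before the data were examined, and 3 of them were primary (type I interferon response, S phase and DNA replication, G2 and mitosis). Lists with at least 5 tested members were compared with other genes by camera of limma 3.58.1, with a preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2. The estimated correlation and fry, which tests whether a list moves on balance in 1 direction, were alternatives. Shares of counts per library were compared by an exact two-sided permutation test, for which 10 splits make 0.1 the smallest p. Calls within 10 Mb of Gabbr1 were compared with calls elsewhere by Fisher's exact test.

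Genes were named by a rule fixed before the data were examined. It took Gabbr1; the 8 genes higher and the 8 lower with the largest change among those past the threshold with mean CPM of at least 5 and groups that did not overlap, without sex-linked, predicted and pseudogenes; the 3 members with the lowest p of each primary or called list; Kit, Ly6a, H2-Ea, Xist, Ddx3y and Gabbr2 as checks; the 2 most abundant members of each list of another cell type; and every list member past the threshold. The text names a selection of these, and says where a gene outside the rule is named.

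Alternatives were other scalings (RLE and upper quartile factors), other filters (none, or CPM of at least 1 in every library), DESeq2 1.42.0, limma-voom, a robust fit, sex as a covariate, gene classes or the Gabbr1 region left out, an adjusted p under 0.1, and each library left out in turn. With 1 WT library left, that library is assumed to vary like the null ones. Leaving out sex chromosome genes or genes of other cell types was added after the data were seen. Replicate numbers follow the order of the samples and pair nothing.

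The code was tested on simulated counts for null over WT with 13192 genes, of which 200 were changed. It recovered 25.4% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 92.4% of those changed 4-fold, and 17 of its 140 calls were unchanged genes. No pair of libraries in a group agreed within sampling noise: the chi-square statistic per degree of freedom was between 8.21 and 13.05.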

Results

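Transcript counts were compared between 2 WT and 3 Gabbr1 null libraries of LSK cells from mice at postnatal day 15, a design that asks how loss of this GABA-B receptor subunit alters gene expression in blood stem and progenitor cells. Total counts were 7980630 and 6972753 in the WT libraries and 7792271, 7530382 and 8150774 in the null libraries. Expression of the sort marker Kit, the receptor for stem cell factor, was 1022 ± 37.7 CPM in WT (SD, n = 2) and 912 ± 66.4 CPM in null (SD, n = 3), and the difference did not pass (edgeR adjusted p = 0.643). Ly6a, which encodes Sca-1, had a log2 fold change of -0.36 ± 0.26 (SE) that did not pass either (edgeR adjusted p = 0.644). Null library 1 had 22532 counts of the X-inactivation transcript Xist and 0 counts summed over 4 Y-linked genes, while the other 4 libraries had at most 21 Xist counts and at least 1140 Y-linked counts.

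Gabbr1 itself (ENSMUSG00000024462.17, chromosome 17, 37045966 to 37075067, mm10) was read in every library. Its counts were 402 and 403 in WT and 289, 264 and 268 in null. Its level was 53.4 ± 5.60 CPM in WT (SD, n = 2) and 35.5 ± 2.79 CPM in null (SD, n = 3), a log2 fold change of -0.59 ± 0.13 (SE) with an edgeR adjusted p of 0.0361. The deleted part of the gene is not given in the sources used here and counts cover the whole gene, so the reads that remained neither check nor contradict the labels. The call was lost without WT library 1, WT library 2, null library 2 or null library 3, with edgeR adjusted p of 0.0722, 0.38, 0.0802 and 0.137. Gabbr2, the partner subunit of the receptor, had between 1 and 3 counts per library and was not tested. Among 6 tested genes of GABA receptors, synthesis and transport, Kctd12, an auxiliary subunit of the GABA-B receptor, rose (log2 fold change 0.55 ± 0.13 SE, edgeR adjusted p = 0.0463), a call lost without any 1 of the 5 libraries.

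Between genotypes, 289 genes were higher and 45 lower in null among 13467 tested (edgeR, adjusted p under 0.05). Of the higher genes, 23 belonged to the fixed lists of other cell types, and of the lower genes 9 belonged to the immediate early list. All 334 called genes had library values that did not overlap between the groups, as did 29.2% of tested genes, where chance gives 20%. 18 of the genes that rose had no count in WT and 35 had 1 to 3 counts. The number of calls rested on having both WT libraries: 101 genes were higher and 37 lower without WT library 1, and 32 higher and 0 lower without WT library 2, where DESeq2 called 139 and 5, limma-voom 0 and 0, and 339 genes were lower at an unadjusted p under 0.05. Without null library 3, 15 genes were lower.

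Most markers of the B lineage rose in null. Of 16 tested markers, 11 were higher and 1 was lower (DESeq2 10 and 0, limma-voom 11 and 0), against 12 higher and 1 lower when adjusted over the list alone. Pax5, the transcription factor that commits cells to the B lineage (chromosome 4, 44524757 to 44710487), increased from 18.1 ± 15.1 CPM in WT (SD, n = 2) to 160 ± 31.8 CPM in null (SD, n = 3), with a log2 fold change of 3.11 ± 0.37 (SE, edgeR adjusted p = 0.000942). The surrogate light chain genes Vpreb1 and Igll1, which are expressed before a mature light chain is made, rose by 3.17 ± 0.44 and 2.94 ± 0.40 on the log2 scale (SE, edgeR adjusted p = 0.00213 and 0.00198). Spib rose by 3.63 ± 0.32 (SE, edgeR adjusted p = 0.000137). In contrast, Igkc, the constant region of the kappa light chain, fell from 246 ± 135 to 76.7 ± 40.7 CPM (SD, n = 2 and 3, edgeR adjusted p = 0.0486), a call absent in DESeq2 and limma-voom and lost without WT library 1, WT library 2 or null library 3. Ighm was 671 ± 233 CPM in WT and 664 ± 73.7 CPM in null (SD, n = 2 and 3). Camera called the list higher (adjusted p = 1.7e-11), with adjusted p = 0.32 with an estimated correlation and 0.037 in fry. Spib passed in every alternative fit that tested it, and Pax5 in all of these but the robust fit, while Vpreb1 and Igll1 were lost without WT library 2.

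Genes of early lymphoid priming moved in both directions. Of 20 tested members, 6 were higher and 1 lower, with 8 and 2 adjusted over the list alone. The recombinase genes Rag1 and Rag2, the interleukin-7 receptor gene Il7r and the B-cell factor Ebf1 rose, with log2 fold changes of 2.28 ± 0.36, 1.73 ± 0.30, 1.83 ± 0.33 and 2.66 ± 0.38 (SE, edgeR adjusted p = 0.00437, 0.00807, 0.0119 and 0.00271). The co-regulator gene Mn1 fell by 0.54 on the log2 scale (SE 0.13, edgeR adjusted p = 0.0471). The list was not called by camera (adjusted p = 0.11), except without null library 2 (0.048). All of these genes lost their call without WT library 2, and Mn1 also in limma-voom and without WT library 1, null library 2 or null library 3. Pax5 was 28.8 CPM in WT library 1 and 7.41 CPM in WT library 2, while Igkc (151 and 341 CPM) and Ighm (506 and 835 CPM) were higher in WT library 2.

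Most endothelial and stromal markers rose in null. Of 13 tested markers, 8 were higher and none lower (DESeq2 7 and 0, limma-voom 7 and 0), against 11 higher and 1 lower adjusted over the list alone. 11 were higher and 1 was lower at an unadjusted p under 0.05. Cdh5, the adhesion molecule of endothelial junctions, increased from 1.16 ± 0.773 to 19.6 ± 2.16 CPM (SD, n = 2 and 3, log2 fold change 4.10 ± 0.34 SE, edgeR adjusted p = 9.62e-05). The VEGF receptor gene Kdr rose by 3.34 ± 0.40 and the matrix gene Sparc by 5.45 ± 0.39 (SE, edgeR adjusted p = 0.000968 and 4.77e-05). Cxcl12, a niche chemokine, rose by 3.60 ± 0.48 (SE, edgeR adjusted p = 0.00174). Lepr, a marker of marrow stroma, had no count in WT and 11 to 18 counts per null library, which is at least 10-fold higher against 3 counts over the WT group, and its call was lost without either WT library. The list median was 3.34, and 3.32 with Lepr at that bound. Pecam1 and Emcn, its most abundant members, had log2 fold changes of 0.30 ± 0.10 and 0.00 ± 0.16 (SE) and did not pass (edgeR adjusted p = 0.211 and 0.998). Camera called the list higher (adjusted p = 1.3e-10), with adjusted p = 0.32 with an estimated correlation and 0.037 in fry.

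The 8 genes with the largest increases under the naming rule were Col2a1, Col10a1, Acan, Mmp13, Tnc, Nid1, Igfbp5 and Sparc, which encode components or remodelling enzymes of extracellular matrix or, for Igfbp5, a growth factor binding protein. Col2a1 and Acan, the collagen and proteoglycan of cartilage, had no count in WT and 40 to 224 and 8 to 146 counts per null library, at least 77.9-fold and 63.8-fold higher against 3 counts over the WT group. Col10a1, the collagen of hypertrophic cartilage, had 1 count in WT and 112 to 723 per null library, a ratio of 1010 (95% exact interval 181 to 39800). Igfbp5 and Nid1 passed in every alternative fit that tested them, which leaves out the stricter filter, while Col2a1, Acan and Col10a1 did not pass in limma-voom or without either WT library.

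**Figure D1:**
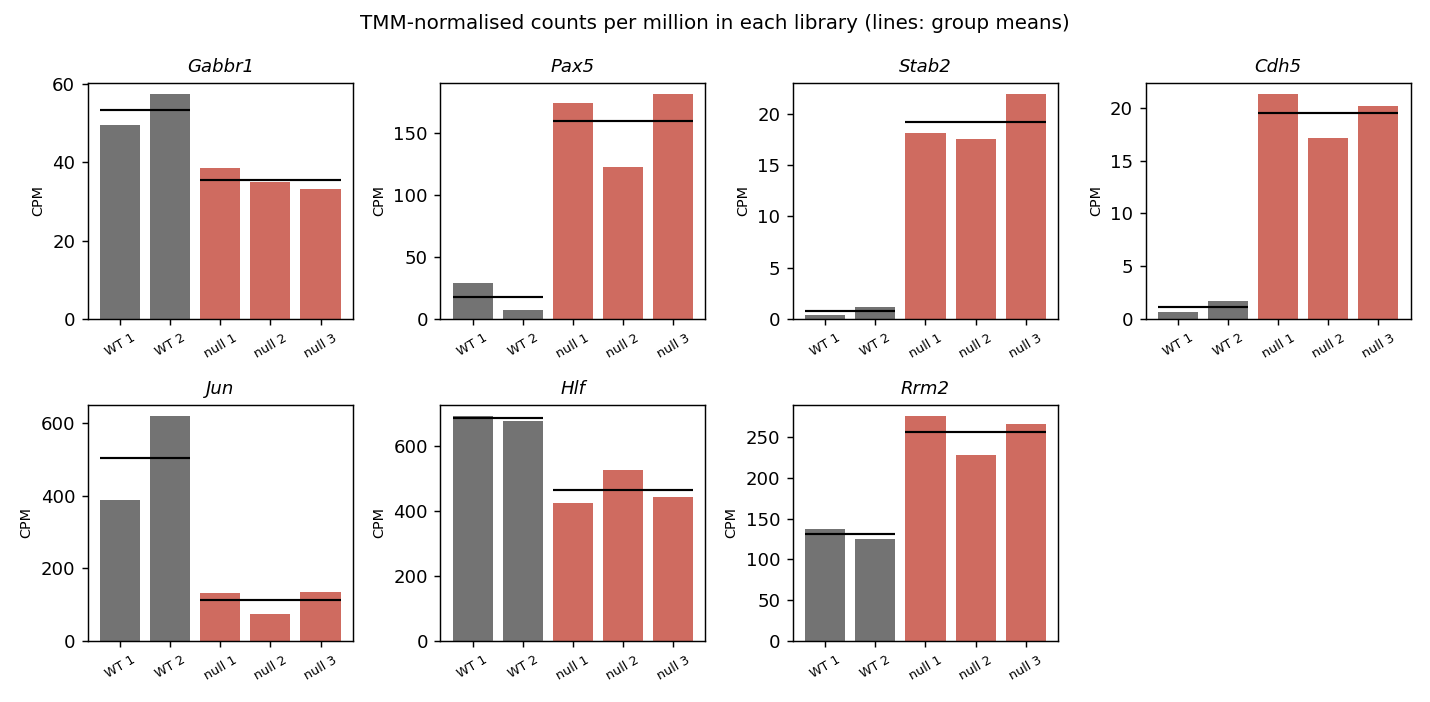
TMM-normalised CPM (vertical axes, from 0) of 7 genes in the 2 WT libraries (grey bars) and the 3 Gabbr1 null libraries (red bars), with horizontal lines at the group means. Pax5 (B lineage), Stab2 and Cdh5 (endothelium) and Rrm2 were higher, and Gabbr1, Jun and Hlf lower, in each null library than in both WT libraries; Stab2 was chosen after its values were seen.

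Immediate early genes, which respond within minutes to growth factors and stress, were lower in part. Of 24 tested members, 9 were lower and none higher (DESeq2 6 and 0, limma-voom 7 and 0; 16 lower and 0 higher at an unadjusted p under 0.05), with 15 lower adjusted over the list alone. Jun, a subunit of the AP-1 transcription factor, fell from 503 ± 163 to 114 ± 33.3 CPM (SD, n = 2 and 3), a log2 fold change of -2.14 ± 0.23 (SE, edgeR adjusted p = 0.000539). Its partner Fos had a log2 fold change of -1.93 ± 0.33, the phosphatase gene Dusp1 -1.46 ± 0.21, and the nuclear receptor gene Nr4a1 -2.24 ± 0.39 (SE, edgeR adjusted p = 0.00807, 0.00246 and 0.00838). Jun, Fos, Dusp1, Nr4a1, Egr1 and Zfp36 were also among the 8 genes with the largest decreases, together with Igkc and Rgs1, a regulator of G-protein signalling (log2 fold change -1.11 ± 0.16 SE, edgeR adjusted p = 0.00282). Levels differed within WT too: Fos was 96.4 CPM in WT library 1 and 239 CPM in WT library 2, and without WT library 2 none of these genes passed in edgeR. Zfp36 was also lost without WT library 1, and Fos, Egr1 and Zfp36 did not pass in DESeq2. The list median relative to the WT mean was -0.32 and 0.32 in WT libraries 1 and 2 and -0.40, -0.87 and -0.72 in null libraries 1, 2 and 3. Camera called the list lower (adjusted p = 3.7e-08), with adjusted p = 0.5 with an estimated correlation.

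Of 29 tested stem cell genes, 4 were lower and none higher (DESeq2 and limma-voom each 4 and 0; 13 lower and 2 higher at an unadjusted p under 0.05), with 11 lower and 2 higher adjusted over the list alone. Hlf, a transcription factor of stem cells, fell from 685 ± 10.3 to 464 ± 54.0 CPM (SD, n = 2 and 3, log2 fold change -0.56 ± 0.13 SE, edgeR adjusted p = 0.0398). The homeobox gene Hoxa9 and Ifitm1 had log2 fold changes of -0.50 ± 0.11 and -0.74 ± 0.14 (SE, edgeR adjusted p = 0.0284 and 0.0158), and these calls were lost without WT library 2. Hlf and Hoxa9 were also lost without WT library 1, null library 1 or null library 3, and Ifitm1 without null library 3. Camera called the list lower (adjusted p = 0.00065), with adjusted p = 0.32 with an estimated correlation and 0.073 in fry. The list had 22 negative and 7 positive members, LSK gate genes had a median of -0.13, and B lineage and endothelial markers were higher in the same null libraries.

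Most proliferation genes had small positive log2 fold changes. In the S phase and DNA replication list, 44 of 47 members had a positive log2 fold change and Rrm2, a subunit of ribonucleotide reductase, rose from 131 ± 8.42 to 257 ± 25.3 CPM (SD, n = 2 and 3, log2 fold change 0.97 ± 0.12 SE, edgeR adjusted p = 0.00109). Its call was lost without WT library 2, and 3 members passed adjusted over the list alone. In the G2 and mitosis list, 40 of 42 members were positive with a median log2 fold change of 0.24, and 0 passed in edgeR, DESeq2 or limma-voom, while 17 were higher and 0 lower at an unadjusted p under 0.05. Ccnb1, the cyclin of mitotic entry, was 99.5 ± 14.0 CPM in WT and 139 ± 24.1 CPM in null (SD, n = 2 and 3, edgeR adjusted p = 0.165). Of 59 replication-dependent histone genes, Hist1h3g and Hist1h2ah rose (log2 fold change 0.74 ± 0.15 and 0.50 ± 0.11 SE, edgeR adjusted p = 0.0222 and 0.0329). DESeq2 called 10 higher and 0 lower and limma-voom 2 and 0, with 30 and 1 at an unadjusted p under 0.05 in edgeR. Both edgeR calls were lost without either WT library, Hist1h2ah also without null library 1 or 2, and 11 histone genes passed adjusted over the list alone. Camera called the 3 lists higher (adjusted p = 0.00023, 8.2e-07 and 5.3e-11), with adjusted p = 0.37, 0.5 and 0.5 with an estimated correlation. B-lineage markers were also higher in each null library. Their log2 medians above the WT mean were 3.05, 2.08 and 3.07 in null libraries 1, 2 and 3. In the same libraries the medians were 0.11, 0.14 and 0.14 for S phase, 0.23, 0.16 and 0.31 for G2 and mitosis, and 0.52, 0.23 and 0.26 for histones. The G2 and mitosis and histone medians were lowest in null library 2, as was the B-lineage median. The S phase median was lowest in null library 1. An order of so few libraries cannot decide whether B-lineage cells contributed these transcripts.

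The type I interferon response was not called. Of 50 tested members, 0 passed in edgeR, DESeq2 or limma-voom, also adjusted over the list alone, and 2 were higher and 0 lower at an unadjusted p under 0.05. The median log2 fold change was 0.03, and camera, whose direction was down, gave an adjusted p of 0.72. The camera result with the preset correlation depended on null library 1. The list median lay 0.36 above the WT mean in null library 1 and at -0.34 and -0.19 in null libraries 2 and 3. Without null library 1, 39 of 49 members were negative with a median of -0.24, and camera called the list lower (adjusted p = 0.00022), with adjusted p = 0.4 with an estimated correlation and 0.23 in fry, and 0 members passed in edgeR, while 11 were lower at an unadjusted p under 0.05. Irf7, the interferon-induced regulator of the response, was 35.9 and 38.0 CPM in WT and 67.55, 22.96 and 33.29 CPM in null libraries 1, 2 and 3; Irf7 was named after its values were seen.

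Myeloid and erythroid priming genes rose in part. Of 25 granulocyte and monocyte priming genes, 5 were higher and none lower (DESeq2 9 and 0, limma-voom 3 and 0; 12 and 1 at an unadjusted p under 0.05), with 11 and 1 adjusted over the list alone. Ctsg and Elane, proteases of neutrophil granules, rose by 1.65 ± 0.23 and 2.67 ± 0.48 (SE, edgeR adjusted p = 0.00204 and 0.0102). Both calls were lost without either WT library, and Elane did not pass in limma-voom. The list median was 0.92 above the WT mean in null library 1 and 0.14 and 0.25 in null libraries 2 and 3. Of 27 megakaryocyte and erythroid priming genes, 6 were higher and none lower (DESeq2 4 and 0, limma-voom 2 and 0; 14 and 2 at an unadjusted p under 0.05), with 12 and 0 adjusted over the list alone. The sphingosine phosphate transporter gene Mfsd2b rose from 9.30 ± 1.47 to 32.6 ± 2.28 CPM (SD, n = 2 and 3, edgeR adjusted p = 0.000335). Camera called both lists higher (adjusted p = 5.3e-05 and 0.00019), with adjusted p = 0.5 and 0.48 with an estimated correlation. Mature erythroid markers had medians of 1.53, 0.78 and 0.07 above the WT mean in null libraries 1, 2 and 3, and of 7 tested 0 passed in edgeR, DESeq2 or limma-voom, with 4 higher at an unadjusted p under 0.05. Of 13 tested markers of mature neutrophils, 0 passed in edgeR, DESeq2 or limma-voom, and 11 were higher and 1 lower at an unadjusted p under 0.05. They differed by library: their summed level was 185 and 143 CPM in WT and 2296, 654 and 158 CPM in null libraries 1, 2 and 3 (exact permutation p = 0.6).

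**Figure D2:**
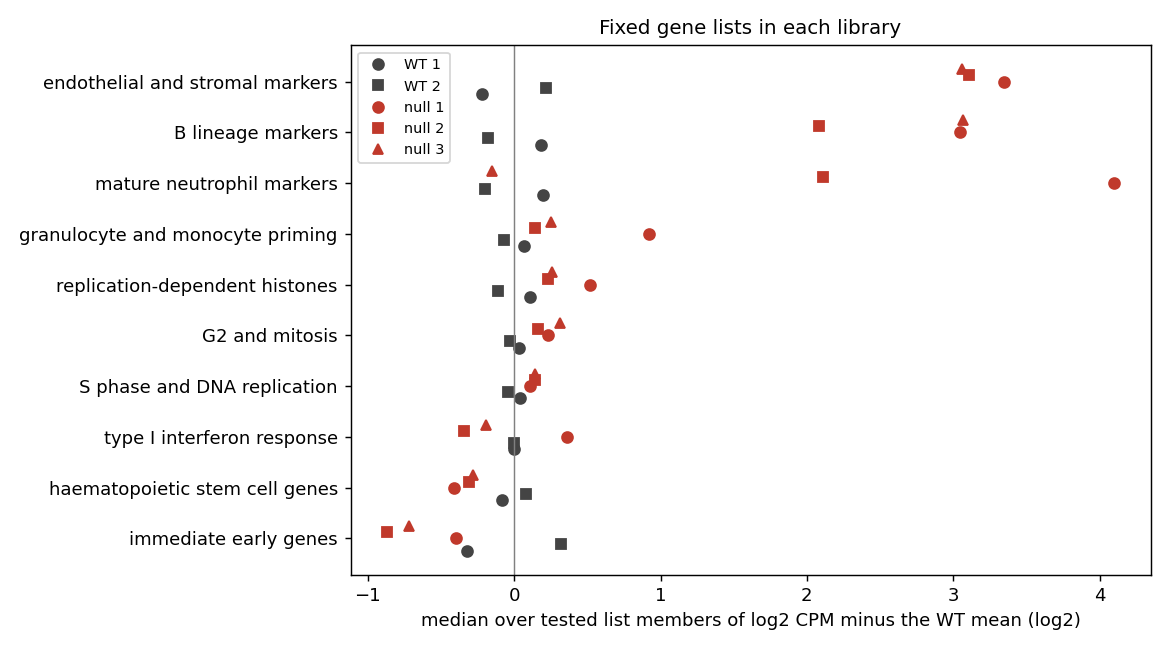
Median over the tested members of 10 fixed gene lists of log2 CPM minus the WT mean (horizontal axis, log2), for each WT library (grey) and each null library (red). B lineage markers lay at 3.05, 2.08 and 3.07 in the null libraries, while mature neutrophil markers lay at 4.1, 2.11 and -0.15.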

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

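Leaving out sex chromosome genes or genes of other cell types was chosen after the result was seen; the splits were planned. Of 83 named genes past the threshold besides Gabbr1, 11 passed with RLE factors, DESeq2, limma-voom, each library left out and, where it kept them, the stricter filter (among them Cdh5, Cxcl12, Igfbp5, Kdr, Mfsd2b, Nid1, Pax5, Scd1, Sparc and Spib), 72 lost the call in at least 1 of these, and none turned direction. The other fits kept the 11 where they tested them, except Pax5 in the robust fit. The stricter filter did not test Cdh5, Cxcl12, Igfbp5, Kdr, Nid1, Scd1 and Sparc. RLE and upper quartile factors, DESeq2, limma-voom, a robust fit, sex as a covariate and the gene classes left out kept both counts of calls within 1.5 times. With no filter, 602 genes were higher and 155 lower. The stricter filter gave 173 higher, 167 of them also called in the first fit. An adjusted p under 0.1 gave 81 lower. Leaving out each library gave 32 to 316 genes higher and 0 to 51 lower, the lowest without WT library 2, where 1 WT library was left. Without genes of other cell types, 257 were higher and 47 lower.

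With an estimated correlation 0 lists were higher and 0 lower in camera (5 lists at an unadjusted p under 0.05, smallest adjusted p 0.32). Fry called 3 lists higher (B lineage, endothelial and stromal, and fatty acid metabolism) and 0 lower. S phase and DNA replication had adjusted p of 0.37 with an estimated correlation and 0.073 in fry, and G2 and mitosis 0.5 and 0.16. Leaving out each library gave 5 to 10 lists lower, adjusted p of 0.00022 to 0.97 for the interferon list, which turned up without WT library 2, null library 2 or null library 3, and 6.7e-05 to 0.86 for cytosolic ribosomal proteins, which turned up without null library 2 (0.059). Gabbr1 ranged from -0.71 to -0.48. The odds ratio near Gabbr1 was 0.823 in a 20 Mb window and 1.045 in a 5 Mb window, and at an unadjusted p under 0.01 it was 1.342 within 10 Mb and 1.721 within 5 Mb (Fisher's exact p = 0.229 and 0.072). Among genes that did not pass, leaving out each library turned the sign of Cd4 (-0.39 to 0.16), Ddx3y (-0.98 to 0.07), Emcn (-0.04 to 0.07), Epx (-2.29 to 0.10, past the threshold without null library 1), Ighm (-0.34 to 0.39) and Lyz2 (-0.17 to 0.58), and Ighm was 0.02 in limma-voom. The cause was not tested.

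The split of the libraries by genotype gave 334 called genes, and the highest of the other splits gave 12. Only 1 of the 10 splits, the real one, gave as many, but 10 splits are too few for a share under 0.05. Depth limits genes under about 1 CPM, which stand on fewer than 10 counts.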

Other observations

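The tests on B progenitor and endothelial cells, on mature B cells, on a lower share of LSK cells, on dilution and on handling were chosen after the result was seen. Those on sex, the female library, the B lineage score and the Gabbr1 region are recorded as written before. The labels give no sex, so the test on the female library followed a look at the Xist and Y-linked counts.

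Among 10 tested MHC class II genes, 3 were higher and none lower (DESeq2 and limma-voom each 1 and 0; 5 and 0 at an unadjusted p under 0.05), with 5 adjusted over the list alone. Of the 3, H2-Aa and H2-Eb1 lie within 10 Mb of Gabbr1, so what stays open about DNA beside that gene applies to them. The invariant chain gene Cd74 rose from 28.6 ± 4.62 to 84.0 ± 39.3 CPM (SD, n = 2 and 3, edgeR adjusted p = 0.0172), a call absent in DESeq2 and lost without either WT library. MHC class II medians were 0.96, 0.62 and 0.46 in null libraries 1, 2 and 3. Monocyte, macrophage and dendritic markers had the same order (1.03, 0.68 and 0.09). So did mature neutrophil (4.1, 2.11 and -0.15), mature erythroid (1.53, 0.78 and 0.07) and mast cell markers (1.71, 0.97 and -0.09), so the order singles out no cell type. Of 26 fatty acid metabolism genes, the desaturase gene Scd1 and the fatty acid transporter gene Cd36 rose by 3.78 ± 0.38 and 2.49 ± 0.37 (SE, edgeR adjusted p = 0.000343 and 0.00321), and fry called the list higher (adjusted p = 0.037), while camera did not (adjusted p = 0.15, and 0.5 with an estimated correlation). The list median was 0.07, 15 members were positive, and these were its only called genes. Itga4, an integrin subunit used in homing, rose by 0.75 ± 0.11 (SE, edgeR adjusted p = 0.00375), among 20 adhesion genes. The NF-kB genes Nfkbiz and Nfkb2 had log2 fold changes of -0.91 ± 0.13 and -0.61 ± 0.14 (SE, edgeR adjusted p = 0.00208 and 0.0349), and Tlr9 rose by 1.29 ± 0.30 (SE, edgeR adjusted p = 0.04), among 25. Vldlr, with a log2 fold change of -0.99 ± 0.15 (SE, edgeR adjusted p = 0.00282), was the 1 called gene of the integrated stress response. Without WT library 2 the calls of Cd36, Itga4, Nfkbiz, Nfkb2, Tlr9 and Vldlr were lost. Nfkb2 was also lost without WT library 1, null library 2 or null library 3. Tlr9 was also lost without WT library 1 or null library 1 and did not pass in limma-voom.

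Camera also called MHC class II, monocyte, macrophage and dendritic markers, and mature neutrophil markers higher (adjusted p = 0.0019, 0.0028 and 0.011), with adjusted p = 0.5, 0.5 and 0.64 with an estimated correlation. It called ribosome biogenesis and Myc targets, the integrated stress response, cholesterol synthesis and cytosolic ribosomal proteins lower (adjusted p = 0.0027, 0.0052, 0.011 and 0.021), with adjusted p = 0.32, 0.5, 0.5 and 0.82 with an estimated correlation. Calls ended for ribosome biogenesis without WT library 1 (0.22), for the integrated stress response without WT library 2 (0.15), for cholesterol synthesis without WT library 1 (0.12) or null library 3 (0.054), and for mature neutrophil markers without WT library 2 (0.1) or null library 1 (0.051). For cytosolic ribosomal proteins the call ended without WT library 1 (0.86) or null library 2 (0.059). Lists not called were the interferon gamma response (0.49), the Gabbr1 neighbourhood (0.063), cell cycle inhibitors (0.24), mature erythroid (0.083), T and NK (0.083) and mast cell (0.24) markers, GABA genes (0.16), cAMP targets (0.18), NF-kB signalling (0.11), the unfolded protein (0.99) and heat shock (0.54) responses, p53 targets (0.81), respiratory chain genes (0.42), mitochondrially encoded mRNA (0.24), glycolysis (0.052), fatty acid metabolism (0.15), adhesion (0.37), cytokine receptors (0.99), LSK gate genes (0.37), noncoding RNA (0.18) and sex-linked genes (0.42), with camera adjusted p in parentheses. Leaving out 1 library called some of them with the preset correlation. These were the Gabbr1 neighbourhood (0.0091 without WT library 1, 0.012 without null library 1), NF-kB signalling (0.024 and 0.023 without the same libraries), cAMP targets and glycolysis (0.019 and 0.043 without WT library 1), heat shock (0.035 without WT library 2) and noncoding RNA (0.013 without null library 1), all lower. Called higher were mitochondrially encoded mRNA (0.025 without WT library 1, 0.023 without null library 1), T and NK markers (0.033 without WT library 2, 0.027 without null library 3), and mature erythroid and mast cell markers (0.031 and 0.018 without null library 3). Respiratory chain genes were called lower without WT library 2 (0.037) or null library 3 (0.0065) and higher without null library 2 (0.024). Sex-linked genes had a median log2 fold change of -0.39 and a mean of 1.95. In ribosome biogenesis, cholesterol synthesis and cytosolic ribosomal proteins 0 genes passed in edgeR, DESeq2 or limma-voom, and 6, 5 and 2 were lower at an unadjusted p under 0.05.

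Cartilage and matrix, endothelial and B-lineage transcripts were among the increases, and lists of further genes were written after this was seen, 21 of whose entries had been seen as values or calls before they were listed. If a lower share of LSK cells raised every other type alike, the medians of B lineage and of T and NK markers would match. The B lineage median was higher by 2.6 on the log2 scale (95% bootstrap interval over genes, not libraries, 0.49 to 3.24). This speaks only to an equal rise, and a lower LSK share with an uneven mix of other cells stays open. Mature B or plasma cells would bring Igkc, whose log2 fold change was -1.68 (95% interval -2.54 to -0.81) in edgeR. Its intervals were -3.17 to -0.21 in DESeq2 and -2.67 to -0.82 in limma-voom. This is 1 gene, chosen after its fall was seen, at 151 and 341 CPM in WT libraries 1 and 2. The B-lineage markers Ms4a1 and Cd22 rose by 4.51 and 2.76 (edgeR adjusted p = 0.00109 and 0.00462), so Igkc cannot decide whether such cells contributed RNA. Among entries not seen before, 1 of 2 B progenitor genes and 5 of 13 endothelial genes were higher at an unadjusted edgeR p under 0.05. Of the 13, 2 were lower. Among all 13467 tested genes, 1076 were higher and 652 lower at that p. These entries are too few to decide whether such cells contributed RNA. Whether other cells passed the gate, or LSK cells of null mice expressed these genes, stays open, and so does an effect of genotype on cell numbers. The purity of the gate is not given in the sources used here. A gate negative for lineage markers is meant to remove mature blood cells and B-lineage cells, which does not concern the cartilage or endothelial genes. Summed mature neutrophil markers were 185 and 143 CPM in WT and 2296, 654 and 158 CPM in null libraries 1, 2 and 3. Summed T and NK markers were 64.5 and 77.3 CPM in WT and 88.5, 76.5 and 71.8 CPM in null. Cartilage genes differed between null libraries 1, 2 and 3, with Acan at 18.5, 19.3 and 0.986 CPM and Col10a1 at 96.3, 93.4 and 13.8 CPM. Endothelial and stromal medians were 3.35, 3.11 and 3.06 above the WT mean on the log2 scale in these libraries.

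The lower immediate early genes were weighed against dilution by RNA of other cells and against handling. If the other cells lacked RNA of the LSK gate genes, dilution would lower immediate early genes no more than gate genes. The immediate early median differed from that of the 6 gate genes by -0.61 on the log2 scale (95% bootstrap interval over genes -1.13 to -0.17). The interval covers spread between genes, not libraries, and whether other cells express the gate genes was not tested, so dilution is not excluded. Time between death and lysis could change these genes and is not recorded, so it cannot be told apart from genotype; the WT libraries differed from each other by a median of 0.63, against -0.74 between genotypes.

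Higher cell cycle and histone genes were weighed against the female library and against cycling B progenitors. Without null library 1 the median log2 fold change of G2 and mitosis genes was 0.22. Camera with the preset correlation still called that list (adjusted p = 2.9e-06, and 0.53 with an estimated correlation). For G2 and mitosis genes, and with the preset correlation, this argues against that library as the cause. Histone genes were not part of this test as written, and their median was 0.52 in null library 1 against 0.23 and 0.26 in null libraries 2 and 3. Without null library 1, camera with the preset correlation also called the histone list higher (adjusted p = 6.9e-07). With all libraries and an estimated correlation, the histone list had a camera adjusted p of 0.5. With a B lineage score as covariate the G2 and mitosis median was 0.09 instead of 0.24. The score followed genotype so closely (correlation 0.96) that B progenitors and genotype cannot be told apart as sources.

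Further planned checks concerned all calls. Sex did not fully separate the genotypes, but the only female library was null. The null over WT ratio of Y-linked CPM, 0.76, reflects that mix and does not test an effect of sex. With sex as a covariate, 84.7% of calls passed (253 of the 289 higher and 30 of the 45 lower). As null library 1 was the only female, the sex term fits that library alone, and genotype is estimated from the male libraries. This fit is thus nearly the same comparison as leaving out that library, and the 2 results are not independent. Without null library 1, the only female, 233 of the higher and 31 of the lower calls passed. Within 10 Mb of Gabbr1, 7 of 278 genes were called, an odds ratio of 1.019 against the rest of the genome (95% interval 0.403 to 2.153, Fisher's exact two-sided p = 0.846), so an effect of flanking strain DNA is neither shown nor excluded. H2-Ea had 0 counts in every library.

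With 10 splits no share of counts could pass, and the smallest exact permutation p of 0.1 was reached by endothelial and stromal markers (null over WT ratio 1.89) and replication-dependent histones. Mitochondrially encoded genes took 0.952% ± 0.224 in WT and 1.06% ± 0.132 in null (SD, n = 2 and 3), and replication-dependent histones 2.72% ± 0.294 and 3.36% ± 0.298.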
